A study of Homo sapiens with 24 samples.

How the data were processed

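Gene expression was measured by RNA sequencing of total RNA from IMR90 cells in 24 libraries, 6 for each of 4 treatments, and the labels call the 6 of a treatment biological replicates. The dose and time of treatment are not given in the sources used here. The table deposited by the authors holds 1 value per gene and library, a normalised signal. From its values, this is the gene's count divided by a size factor of its library. Per the submitters' processing notes, STAR 2.7.3a, HTSeq 0.13.5, DESeq2 1.32.0 and build hg38 were used, with no role or order stated. The strand setting and the annotation behind the counts are not given in the sources used here. Reads of genes that overlap, on either strand, and of near-identical copies such as HSPA1A and HSPA1B or HSPA6 and HSPA7 may therefore not be separable.

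Each value was a whole multiple of the worth of 1 read in its library, and 100% of values gave whole reads within a tolerance of 0.01. That worth is closest to 1 in vehicle 4 and in cortisol and relacorilant 5, where 4.79% and 8.22% of values would be whole at a worth of exactly 1, against 0.894% to 1.60% in the other libraries. Recovered totals were 17810712 to 28863972 reads per library. Floors of 3 reads per library were used for groups with no read, and these and all depths cover counting error only. The table lists 60683 genes, of which 23221 had no read in any library. A table of gene names matched 60370 of the identifiers, and GENCODE release 29, used for coordinates, neighbours and GC content, matched 58496. None of the library pairs within groups were duplicates, with a chi-square per degree of freedom of 3.62 to 124 over 60 pairs.

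The 15050 genes with a mean of at least 10 over the 24 libraries were tested, 14199 of them with a symbol. limma 3.58.1 in R 4.3.3 was fitted to log2(value + 1) with a mean-variance trend, all 24 libraries and no covariate. Adjusted p-values are limma's with Benjamini-Hochberg adjustment, two-sided, and the threshold was 0.05. A fold change is on the log2(value + 1) scale, which understates the change of genes with few reads. The comparisons were cortisol, relacorilant and the combination against vehicle, the combination against each compound, and the interaction. Because the table holds normalised values, the count tests of edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives. For cortisol against vehicle they called 5198 and 5483 genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

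The share of the cortisol effect left with relacorilant was the median ratio of log2 fold changes over the genes called with cortisol, with the SD of 1000 resamples of libraries within groups. Choosing genes on the denominator can bias it low for weak genes. Comparisons against the same vehicle libraries were set beside 100 simulations of unchanged groups and 20 splits of the vehicle libraries.

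Of 26 gene lists, 24 had at least 5 tested genes and were tested with camera in limma at a preset correlation of 0.01. The lists were those of glucocorticoid-induced genes, cytokines, NF-kB, interferon, matrix, proteases, contractile genes, DNA replication, mitosis, p53 and CDK inhibitors. Others were of cholesterol synthesis, adipogenic genes, metallothioneins, hypoxia, unfolded protein stress, clock genes, the receptor and its partners, aryl hydrocarbon and NRF2, DNA methylation, WNT and growth factors, mitochondrial mRNAs, and epithelial, endothelial, blood and pericyte markers. Calls that held with an estimated correlation were those of glucocorticoid-induced, adipogenic and WNT, BMP and growth factor genes with cortisol and of matrix proteases with relacorilant.

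The groups, tests, lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, for cortisol or relacorilant against vehicle and for the combination against cortisol, the 8 genes each way with the highest and lowest fold change among those past the threshold with a mean of at least 50 in the higher group and a symbol, up to 4 members of each list described by smallest p, and always FKBP5, TSC22D3, PER1, ZBTB16 and NR3C1. Other comparisons took 5 each way. Some genes taken by the rule are not reported here. Which lists to describe member by member was decided after the list results were seen. List tests in comparisons other than these 3 were added later, with their alternatives. DESeq2 gave no list test. The alternatives set then were pseudocounts of 0.5 and 5, no filter and a minimum mean of 50, quantile and upper-quartile scaling, fits of only the groups compared, the replicate number as a block, both count tests and an estimated correlation. A fit without vehicle 4, relacorilant 3 and relacorilant 4, removal of the trend on GC content, which 99.3% of tested genes had a value for, and a list of 24 heat-shock genes were added after seeing the data. A count was held the same within 1.5 times.

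The tests were tried on simulated data in 5 draws over 15050 genes for cortisol against vehicle, with 200 changed genes. limma recovered 48.8% of genes with a log2 change of 0.5 and 75.2% with a change of 1, and 5.96% of its calls were unchanged genes. edgeR recovered 48% and 74.8%, with 5.36% of calls unchanged genes. A share of 0.25 was recovered as 0.237. camera gave a raised list of 30 genes a p of at most 1.20e-25 and an unchanged list a p of at least 0.272. Genes were drawn independently of each other and no library stood apart, so the trial does not test camera on correlated genes. Far fewer genes were changed in it than were called in the data.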

Results

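The transcriptome of IMR90 cells, an established line of human fetal lung fibroblasts, was measured by RNA sequencing after 4 treatments. These were a vehicle control, cortisol (the main human glucocorticoid), relacorilant (a synthetic antagonist of the glucocorticoid receptor), and cortisol together with relacorilant. Each group held 6 biological replicates, so that the table covered 24 libraries. The dose and duration of the treatments are not given in the sources used here. The libraries held 17810712 to 28863972 reads assigned to genes. Group means were 22515030 ± 883382 for vehicle, 21757938 ± 2078263 for cortisol, 25714830 ± 1716339 for relacorilant and 25253704 ± 2543885 for the combination (SD, n = 6 each). Of 60683 listed genes, 15050 had a mean normalised read count of at least 10 and were tested.

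The 4 groups separated along the first 2 principal components, which carried 32.8% and 18.3% of the variance. Vehicle 4, relacorilant 3 and relacorilant 4 lay away from the other libraries of their groups on the second component, with scores of 93.7, 32.3 and 35.9. Reads of mitochondrially encoded genes made up 5.01% to 5.13% of these 3 libraries and 2.90% to 4.00% of the other 21. Among markers of other cell types, 7 of 20 epithelial, 7 of 15 endothelial, 2 of 19 blood and immune, and 12 of 14 pericyte and smooth muscle genes passed the minimum count.

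**Figure D1:**
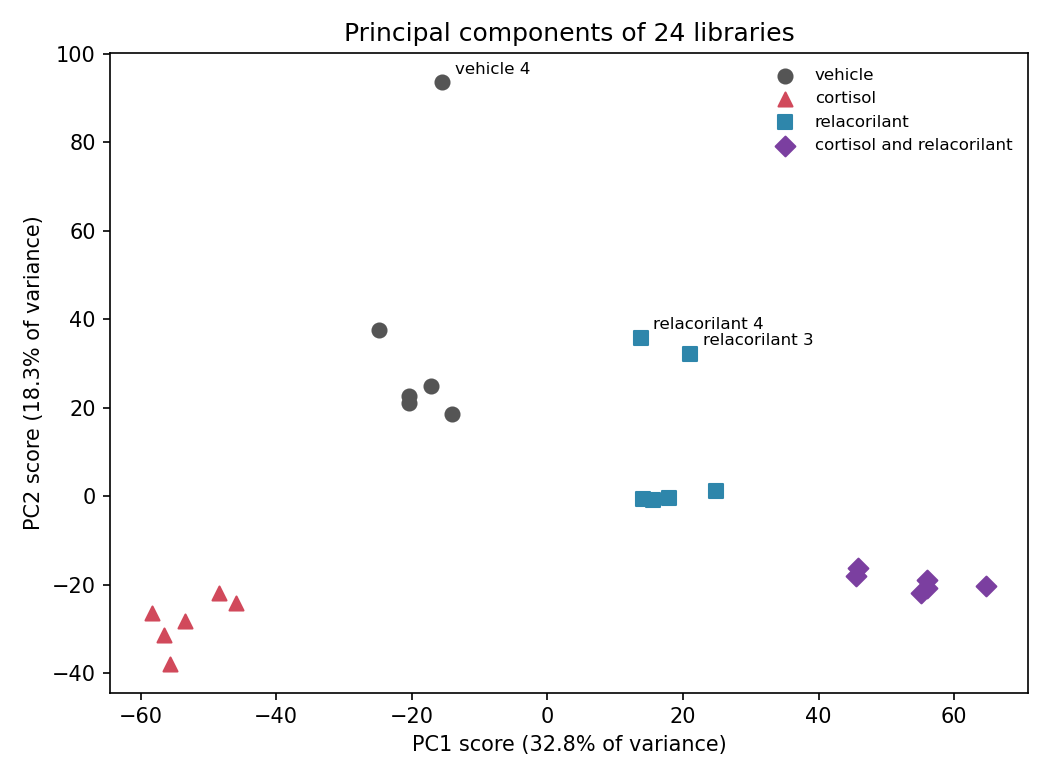
Scores of the 24 libraries on the first 2 principal components of log2(normalised read count + 1), with 1 point per library and the percent of variance on each axis. Cortisol libraries sit at the lowest scores of PC1 and the combination at the highest, and vehicle 4 has a PC2 score of 93.7.

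Cortisol was compared with vehicle to describe the response of these fibroblasts to the hormone. FKBP5, a co-chaperone of the glucocorticoid receptor and a classical target of it (ENSG00000096060, chromosome 6, 35573585 to 35728583), rose from 241 ± 88.8 to 3139 ± 236 normalised reads (SD, n = 6; log2 fold change 3.77 ± 0.15 SE, adjusted p = 1.64e-16). ZBTB16, a zinc finger transcription factor (ENSG00000109906, chromosome 11, 114059593 to 114250676), had no read in any vehicle library and 872 ± 224 normalised reads with cortisol, at least 277-fold higher when vehicle is set to 3 reads per library. TSC22D3, which encodes the anti-inflammatory protein GILZ (ENSG00000157514, chromosome X, 107713221 to 107777342), rose from 394 ± 42.6 to 1167 ± 245 (log2 fold change 1.54 ± 0.11). The clock gene PER1 (ENSG00000179094, chromosome 17, 8140472 to 8156506) rose from 696 ± 207 to 1644 ± 215 (log2 fold change 1.29 ± 0.19). Coordinates are of build hg38 in GENCODE release 29, and each covers the whole gene. NR3C1, the gene of the receptor itself (ENSG00000113580, chromosome 5, 143277931 to 143435512), stood at 1853 ± 285 with vehicle and 1628 ± 83.7 with cortisol and did not pass the test (log2 fold change -0.18 ± 0.08, adjusted p = 0.0842). It passed with the replicate number as a block (adjusted p = 0.0327, 0.0327 to 0.182 over the alternatives). The vehicle mean of NR3C1 includes vehicle 4 at 2411, above 1636 to 1858 in the other vehicle libraries.

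In all, 5264 of the 15050 genes changed with cortisol by the limma test at an adjusted p below 0.05, 2579 higher and 2685 lower, and 1116 of these changed by at least 2-fold. The largest increase after ZBTB16 was in ADH1B, an alcohol dehydrogenase (ENSG00000196616, chromosome 4, 99304964 to 99352760), from 31.8 ± 25.5 to 3746 ± 398 (log2 fold change 7.29 ± 0.59, adjusted p = 2.11e-10). CILP, an extracellular protein of cartilage, came next and rose from 1.06 ± 1.73 to 119 ± 41.0. The long noncoding RNA LINC02893 rose from 0.330 ± 0.809 to 57.2 ± 22.7. The chemokine CCL11, the prostaglandin D2 receptor PTGDR2 and LCNL1 followed, with log2 fold changes of 4.75, 4.73 and 4.61. PTGDR2 overlaps CCDC86 on the opposite strand. The largest decrease was in ITGA8, an integrin subunit (ENSG00000077943, chromosome 10, 15513949 to 15720125), from 222 ± 106 to 2.88 ± 2.28 (log2 fold change -5.87 ± 0.49, adjusted p = 3.87e-10). LINC01915, DDIT4L, the cell adhesion molecule L1CAM, BMP2, MMP3, TMEM176A and UNC13A followed, with log2 fold changes between -5.07 and -4.25. BMP2, a bone morphogenetic protein, fell from 332 ± 154 to 14.1 ± 9.63, and the stromelysin gene MMP3 from 417 ± 200.6 to 24.5 ± 19.4. TMEM176A overlaps its neighbour TMEM176B on the other strand, so that their reads may not be separable.

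Of the list of glucocorticoid-induced genes, 20 of 30 measured members rose and 3 fell (20 and 3 adjusted over the list alone). Its median log2 fold change, which does not move with ZBTB16 at its lower bound, was 0.46 (camera adjusted p = 3.03e-06, and adjusted p = 0.0427 with an estimated correlation). Besides FKBP5 and ZBTB16 its members with the smallest p were MAOA, a monoamine oxidase, which rose from 29.8 ± 12.04 to 657 ± 91.5, and CRISPLD2, which rose from 925 ± 118 to 3393 ± 689. Adipogenic and lipid storage genes also moved up: 13 of 24 measured members rose and 4 fell (14 and 4 adjusted over the list alone). The median stood at 0.51 (adjusted p = 0.00246, and adjusted p = 0.0427 with an estimated correlation). APOE rose from 106 ± 50.4 to 1168 ± 241 and the desaturase SCD from 5961 ± 719.7 to 13860.0 ± 1283. SREBF1, a regulator of fatty acid synthesis, rose by 1.30 ± 0.16 on the log2 scale, and PPARG, the master regulator of adipogenesis, by 1.20 ± 0.11. Means of these lists in vehicle 4 lay -0.45 (glucocorticoid-induced genes) and -0.41 (adipogenic genes) from those of the other vehicle libraries on the log2 scale.

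Genes of WNT, BMP and growth factor signalling moved down with cortisol: 8 of 38 measured members rose and 21 fell (8 and 21 adjusted over the list alone). The list median was -0.49 (adjusted p = 0.000200, and adjusted p = 0.0427 with an estimated correlation). FGF7 fell from 2464 ± 199 to 754 ± 167 and the WNT antagonist SFRP1 from 21825 ± 3115 to 9263 ± 1675, whereas WNT2B rose from 48.8 ± 17.9 to 246 ± 58.2. For extracellular matrix structural genes, 25 of 49 measured members rose and 10 fell (26 and 12 adjusted over the list alone). The median of the list was 0.41 (adjusted p = 0.00453, but adjusted p = 0.619 with an estimated correlation). FBN2, FBLN1 and MFAP4, components of elastic fibres, rose by 2.12 ± 0.11, 2.10 ± 0.13 and 1.83 ± 0.13 on the log2 scale, and the matricellular gene THBS1 fell from 100230.0 ± 6886 to 46818 ± 1369.7. Relative to the other vehicle libraries, vehicle 4 averaged -0.55 over the matrix list and -0.25 over the WNT, BMP and growth factor list. Matrix proteases and inhibitors as a list did not pass the test (adjusted p = 0.147), although 8 of 26 measured members rose and 11 fell (8 and 11 adjusted over the list alone). The list passed with no filter and with edgeR (adjusted p = 0.00445 and 0.0181, 0.00445 to 0.523 over all alternatives). Among them the metalloproteinase inhibitor TIMP1 fell from 33878 ± 4561 to 8737 ± 489, SERPINE2 from 4607 ± 820.3 to 861 ± 172 and the urokinase gene PLAU from 11630.0 ± 1327 to 5163 ± 689, while the procollagen peptidase ADAMTS2 rose from 2602 ± 283 to 8970.3 ± 1293.

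Hypoxia and glycolysis genes were higher with cortisol: 18 of 30 measured members rose and 4 fell (19 and 5 adjusted over the list alone). Their median log2 fold change was 0.32 (adjusted p = 0.000430, but adjusted p = 0.523 with an estimated correlation). The carbonic anhydrase CA12 rose from 643 ± 138 to 1969.6 ± 167, ADM from 3931 ± 715 to 7766 ± 831 and VEGFA from 2442 ± 389 to 4196 ± 574, whereas the pyruvate kinase PKM fell from 67904 ± 4392 to 52961 ± 2673. In the aryl hydrocarbon and NRF2 list, 8 of 18 measured members rose and 4 fell (8 and 4 adjusted over the list alone). The median was 0.28 (adjusted p = 0.0436, but adjusted p = 0.523 with an estimated correlation). CYP1B1 rose from 148 ± 44.1 to 1714 ± 166 and the heme oxygenase HMOX1 from 635 ± 154 to 1651 ± 199.5. TKT rose by 0.93 ± 0.07 and ABCC3 by 0.81 ± 0.10 on the log2 scale. Vehicle 4 lay -0.30 from the other vehicle libraries in the mean of the hypoxia list and -0.54 in that of the aryl hydrocarbon and NRF2 list. The latter call was lost in a fit of the vehicle and cortisol libraries alone (adjusted p = 0.0772), with the replicate number as a block (adjusted p = 0.0621) and without the 3 libraries that stood apart (adjusted p = 0.0966). Its adjusted p ran from 0.00206 to 0.523 over the alternatives.

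Mitosis genes were lower with cortisol as a list when all libraries were used: 0 of 37 measured members rose and 7 fell (0 and 5 adjusted over the list alone). Of all 15050 tested genes 2579 rose and 2685 fell. The median of the mitosis list stood at -0.36 (adjusted p = 0.00818, but adjusted p = 0.818 with an estimated correlation). AURKA fell from 1161 ± 196 to 708 ± 212, KIF23 from 832 ± 351 to 503 ± 145, TTK from 234 ± 114 to 130.2 ± 41.1 and KIF20A from 739 ± 230.0 to 484 ± 169. Vehicle 4 averaged 0.86 higher than the other vehicle libraries on the log2 scale over this list. Without the 3 libraries that stood apart the list did not pass (adjusted p = 0.156, 4.68e-05 to 0.818 over all alternatives). KIF20A did not pass in a fit of the vehicle and cortisol libraries alone (adjusted p = 0.0675, 0.00901 to 0.0675 over all alternatives). Of mitochondrially encoded mRNAs, 0 of 13 measured members rose and 6 fell (0 and 7 adjusted over the list alone). The list median was -0.28 (adjusted p = 0.00837, but adjusted p = 0.523 with an estimated correlation). MT-CO2, MT-ND2, MT-ND5 and MT-CO3 had log2 fold changes of -0.42, -0.31, -0.29 and -0.27, the last of which did not pass with quantile normalisation (adjusted p = 0.239, 0.00817 to 0.239 over all alternatives). The mean of this list in vehicle 4 was 0.08 above the other vehicle libraries.

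The remaining lists did not pass the test for cortisol against vehicle. Contractile, DNA replication, p53 and CDK inhibitor lists passed with no filter, CDK inhibitors also with edgeR, and contractile genes also without the 3 libraries and with the GC trend removed. Over all alternatives their adjusted p ran from 0.00783 to 0.545, 0.00529 to 0.826, 0.0486 to 0.523 and 0.0104 to 0.523. Members rose and fell, respectively, in numbers of 1 and 8 of 42 DNA replication genes and 5 and 11 of 31 contractile and TGF-beta response genes (adjusted p = 0.114 and 0.114). They did so in 4 and 7 of 21 CDK inhibitors and senescence-associated genes and 10 and 5 of 26 p53 target genes (adjusted p = 0.142 and 0.147). For unfolded protein and amino acid stress genes these numbers were 11 and 9 of 26, and for cholesterol synthesis 6 and 5 of 25. For DNA methylation machinery they were 5 and 0 of 18, and for circadian clock genes 3 and 3 of 17. Inflammatory lists gave 2 and 3 of 15 for cytokines and chemokines, 2 and 2 of 18 for NF-kB response genes and 6 and 3 of 21 for interferon response genes. Genes of the receptor, its partners and steroid enzymes gave 7 and 7 of 20. Among cell type markers, 0 epithelial genes rose and 2 fell, 1 endothelial gene rose and 0 fell, and 4 pericyte and smooth muscle genes rose and 3 fell (adjusted p = 0.236, 0.753 and 0.919). Metallothioneins, with 2 of 4 measured members lower, and blood and immune markers, with 1 of 2 higher and 1 lower, were too few to test as lists. For each list that passed in any comparison the median, mean and test had the same sign. They differed in sign in this comparison for 5 lists that did not pass, namely cytokines, NF-kB, cholesterol synthesis, epithelial markers and the receptor and its partners. The 51 named genes that changed, chosen for passing the test, had 6 of 6 cortisol libraries past the vehicle mean, and in 45 of them the groups did not overlap (by chance in 0.216% of genes not chosen by their change).

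**Figure D2:**
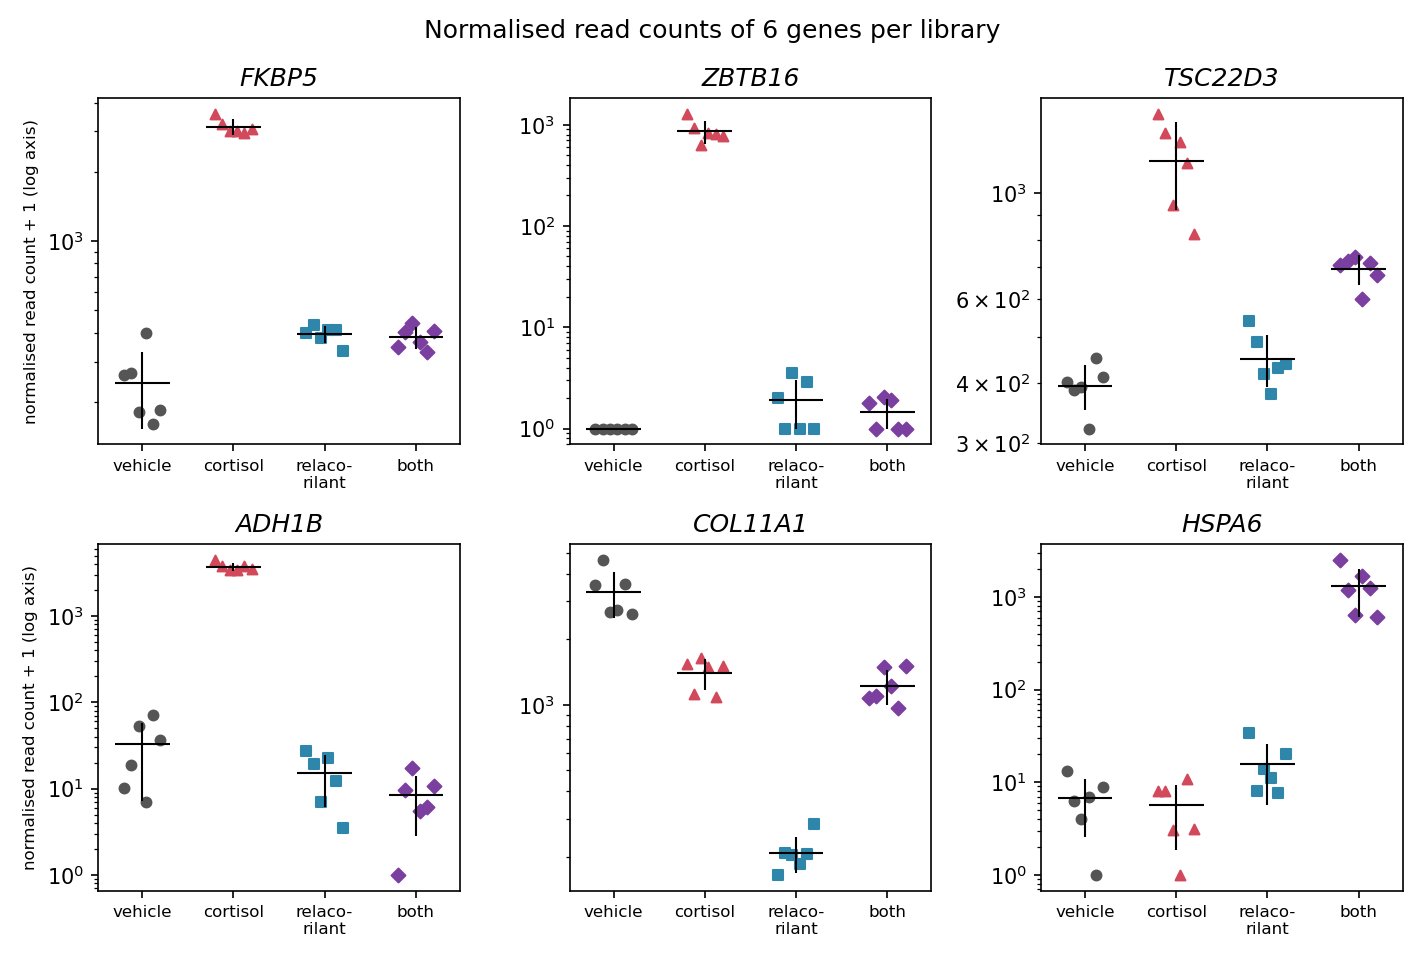
Normalised read count + 1 of 6 genes in each library (log axis), with 1 point per library, a horizontal bar at the group mean and a vertical bar of 1 SD, for n = 6 per group. ZBTB16 had no read in any vehicle library and a mean of 872 with cortisol, and HSPA6 had a mean of 1319 with both compounds.

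Relacorilant alone was compared with vehicle to describe its effect with no hormone added. COL11A1, a fibrillar collagen (ENSG00000060718, chromosome 1, 102876467 to 103108872), fell from 3292 ± 789.9 to 208 ± 39.6 normalised reads (SD, n = 6; log2 fold change -3.97 ± 0.15 SE, adjusted p = 2.49e-16). LRRK2, the transporter SLC6A15, the cytokine TNFSF18 and the lipoprotein receptor gene LRP1B fell with log2 fold changes of -5.46, -4.29, -4.29 and -4.23. ITGA8 fell as well, at -4.44, as did the overlapping TMEM176A and TMEM176B, at -4.21 and -4.27. The largest increase was in LIMCH1, an actin-associated protein (ENSG00000064042, chromosome 4, 41359607 to 41700044), from 2.08 ± 1.45 to 121 ± 49.2 (log2 fold change 5.36 ± 0.39, adjusted p = 3.33e-10). C9, which overlaps the highly expressed DAB2 on the same strand, rose from 3.74 ± 3.78 to 74.9 ± 6.45. C1orf115, the pseudogene NOC2LP1, EPPK1, GNAZ, the corticotropin-releasing hormone binding protein CRHBP and FAM180A rose with log2 fold changes between 2.11 and 3.53.

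Of the 15050 genes, 3127 changed with relacorilant alone, 1562 higher and 1565 lower, and 718 by at least 2-fold. In a fit of the vehicle and relacorilant libraries alone the count was 2034. FKBP5 was 393 ± 33.6 with relacorilant (log2 fold change 0.77 ± 0.15, adjusted p = 0.000321). TSC22D3 and PER1 stood at 449 ± 56.6 and 686 ± 209 and did not pass (adjusted p = 0.281 and 0.977). ZBTB16 had 6 reads over the 6 libraries. NR3C1 fell to 1575 ± 157 (log2 fold change -0.23 ± 0.08, adjusted p = 0.0397). This call was lost with no filter, with upper-quartile scaling and in a fit of these groups alone (adjusted p = 0.0919, 0.0586 and 0.148, 0.00263 to 0.148 over all alternatives).

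Extracellular matrix genes were lower with relacorilant: 3 of 49 measured members rose and 34 fell (3 and 34 adjusted over the list alone). The median of the list was -0.65 (adjusted p = 1.31e-13, but adjusted p = 0.181 with an estimated correlation). Besides COL11A1, COL12A1 fell from 69775 ± 11191 to 30647 ± 2307, COL5A2 from 29773 ± 4426 to 14555 ± 1106 and the proteoglycan VCAN from 9066 ± 2203 to 3773 ± 704. Matrix proteases and inhibitors moved the same way: 2 of 26 measured members rose and 13 fell (3 and 13 adjusted over the list alone). Their median log2 fold change was -0.39 (adjusted p = 4.60e-05, and adjusted p = 0.0130 with an estimated correlation). SERPINE2, PLAU, the gelatinase MMP2 and the cathepsin CTSK fell with log2 fold changes of -1.44, -0.82, -0.69 and -1.57. For contractile and TGF-beta response genes, 1 of 31 measured members rose and 16 fell (1 and 18 adjusted over the list alone). The median was -0.32 (adjusted p = 3.16e-06, but adjusted p = 0.0732 with an estimated correlation). ACTA2, the smooth muscle actin, fell from 4650.4 ± 1263 to 2068 ± 220.1, TGFBI from 50606 ± 7378 to 27663 ± 2492 and CCN1 from 29900.0 ± 2211 to 18874 ± 1499. Relative to the other libraries of their groups, the matrix list averaged -0.55 in vehicle 4, -0.20 in relacorilant 3 and -0.17 in relacorilant 4. The contractile list averaged -0.28, -0.10 and -0.14, and the protease list -0.06, -0.04 and -0.07.

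Unfolded protein and amino acid stress genes were lower: 1 of 26 measured members rose and 17 fell (1 and 18 adjusted over the list alone). The median stood at -0.29 (adjusted p = 4.60e-09, but adjusted p = 0.0732 with an estimated correlation). The chaperones PDIA4, HYOU1 and PDIA6 fell with log2 fold changes of -0.66, -0.49 and -0.42, and CHAC1 fell from 1687 ± 633 to 478 ± 108. Lists of NF-kB response genes and of cytokines and chemokines were also lower. Interferon response genes did not pass as a list (camera adjusted p = 0.633, and 0.0491 with no filter). Of NF-kB response genes, 1 of 18 measured members rose and 7 fell (1 and 10 adjusted over the list alone). The list median was -0.55 (adjusted p = 0.00138, but adjusted p = 0.376 with an estimated correlation). Of cytokines and chemokines, 0 of 15 measured members rose and 6 fell (1 and 7 adjusted over the list alone). The median of the list was -0.85 (adjusted p = 0.00293, but adjusted p = 0.406 with an estimated correlation). NFKBIZ fell from 2691 ± 407 to 947 ± 140.0, NFKBIA from 1429.8 ± 287 to 656 ± 66.9, TNFAIP3 from 643 ± 190.2 to 275 ± 43.4 and IL6 from 767 ± 48.6 to 228 ± 93.7. TSLP, CXCL2 and CSF1 fell with log2 fold changes of -1.36, -1.43 and -0.73, whereas TNIP1 rose by 0.36 ± 0.05. In vehicle 4 the means of the stress, NF-kB and cytokine lists lay -0.37, -0.42 and -0.66 from the other vehicle libraries. In relacorilant 3 they lay -0.12, -0.26 and -0.40 from the other relacorilant libraries, and in relacorilant 4 -0.14, -0.08 and -0.13.

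Hypoxia and glycolysis genes were higher with relacorilant: 16 of 30 measured members rose and 5 fell (18 and 5 adjusted over the list alone). Their median log2 fold change was 0.23 (adjusted p = 0.000868, but adjusted p = 0.412 with an estimated correlation). CA12 rose from 643 ± 138 to 1457 ± 59.0, PDK1 from 719 ± 133 to 1109 ± 119 and BNIP3L from 3939.6 ± 239 to 5055 ± 336, while P4HA2 fell from 4064 ± 247 to 3132 ± 112. Of p53 target genes, 5 of 26 measured members rose and 1 fell (5 and 1 adjusted over the list alone). The median was 0.13 (adjusted p = 0.0398, but adjusted p = 0.258 with an estimated correlation). EDA2R, TIGAR, POLH and CCNG1 rose with log2 fold changes of 1.09, 0.72, 0.42 and 0.25. Relative to the other libraries of their groups, vehicle 4, relacorilant 3 and relacorilant 4 averaged -0.30, -0.13 and -0.04 over the hypoxia list and -0.48, -0.21 and -0.20 over the p53 list. The latter did not pass in a fit of these groups alone (adjusted p = 0.0573, 0.00946 to 0.258 over all alternatives). Of WNT, BMP and growth factor genes, 9 of 38 measured members rose and 16 fell (9 and 16 adjusted over the list alone). The median stood at -0.19 (adjusted p = 0.0367, but adjusted p = 0.258 with an estimated correlation). HGF fell from 4114 ± 528 to 879.6 ± 258, IGF2 from 127 ± 36.1 to 23.7 ± 9.31 and PDGFRA from 5762 ± 1196 to 2755 ± 329.7, whereas WNT5B rose from 3745 ± 343 to 6112 ± 541. This list did not pass with a minimum mean of 50 or without the 3 libraries that stood apart (adjusted p = 0.255 and 0.0704, 0.00414 to 0.258 over all alternatives). Mitosis genes passed as a list (median -0.27, adjusted p = 0.0204, but adjusted p = 0.645 with an estimated correlation), although 0 of 37 members rose and 0 fell by limma. The counts were 0 and 3 at an unadjusted p below 0.05, 0 and 0 with edgeR and 0 and 3 with DESeq2. The list did not pass without the 3 libraries (adjusted p = 0.209, 0.000937 to 0.645 over all alternatives). Those libraries averaged 0.86, -0.04 and 0.34 over the mitosis list and -0.25, -0.17 and -0.03 over the WNT, BMP and growth factor list. The 52 named genes that changed, likewise chosen for passing, had 6 of 6 relacorilant libraries past the vehicle mean, and in 44 of them the groups did not overlap (0.216% by chance for genes not so chosen).

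The other lists did not pass with relacorilant when all libraries were used with the minimum mean of 10. Of glucocorticoid-induced genes, 4 of 30 measured members rose and 7 fell (4 and 7 adjusted over the list alone). Their adjusted p was 0.222, and 0.0441 to 0.598 over all alternatives, below 0.05 with no filter. Mitochondrially encoded mRNAs had a median of -0.05 (adjusted p = 0.220), and passed without the 3 libraries, with a median of -0.18 (adjusted p = 0.000550, 0.000550 to 0.779 over all alternatives). Cholesterol synthesis genes had a median of 0.14 (adjusted p = 0.0802), and passed without the 3 libraries and with no filter (adjusted p = 0.0221 and 0.0263, 0.0221 to 0.592 over all alternatives). Among cell type markers, 1 of 12 pericyte and smooth muscle genes rose and 4 fell (adjusted p = 0.228), and 5 of these 12 are also in the contractile list. Of endothelial markers, 2 of 7 rose and 0 fell, with a median of 0.75 (adjusted p = 0.0809). That list passed with no filter and in a fit of these groups alone (adjusted p = 0.00898 and 0.0423, 0.00898 to 0.412 over all alternatives). Vehicle 4, relacorilant 3 and relacorilant 4 lay -0.28, -0.45 and -1.07 from the other libraries of their groups over the endothelial list and 0.08, 0.40 and 0.43 over the mitochondrially encoded mRNAs. By limma 0 of 7 epithelial markers rose and 0 fell, with 0 and 0 at an unadjusted p below 0.05, 0 and 0 with edgeR and 0 and 1 with DESeq2 (adjusted p = 0.649 for the list). Of 2 blood and immune markers, 1 rose.

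Adding relacorilant to cortisol was compared with cortisol alone to describe the effect of the antagonist on hormone-treated cells. FKBP5, which cortisol raised, fell from 3139 ± 236 to 382 ± 42.6 (SD, n = 6; log2 fold change -3.04 ± 0.15 SE, adjusted p = 5.03e-15). ADH1B fell from 3746 ± 398 to 7.38 ± 5.60, and ZBTB16 from 872 ± 224 to 3 reads over the 6 libraries. TSC22D3 fell from 1167 ± 245 to 692 ± 49.0 and PER1 from 1644 ± 215 to 761 ± 108, with log2 fold changes of -0.73 ± 0.11 and -1.11 ± 0.19. SLITRK6, CCL11, MAOA, SLITRK5, C1QL1 and the phosphodiesterase PDE1A fell with log2 fold changes of -6.52, -5.48, -5.03, -4.87, -4.65 and -4.61. HSPA6, a stress-inducible heat-shock protein (ENSG00000173110, chromosome 1, 161524540 to 161526910), rose from 4.65 ± 3.79 to 1319 ± 711 (log2 fold change 8.08 ± 0.57, adjusted p = 7.65e-12). NR3C1 stood at 1489.9 ± 90.7 against 1628 ± 83.7 and did not pass (adjusted p = 0.171). It passed with quantile normalisation, in a fit of these groups alone and without the 3 libraries that stood apart (adjusted p = 0.0277, 0.0338 and 0.0217, 0.0217 to 0.283 over all alternatives).

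This comparison had the largest number of changed genes of the 5 pairwise comparisons, 8360 of 15050, with 4273 higher and 4087 lower and 2343 changed by at least 2-fold. After HSPA6, whose reads may be shared with its near-identical copy HSPA7, the largest increases were in genes with few reads with cortisol. The sodium-calcium exchanger SLC8A2 (ENSG00000118160, chromosome 19, 47428017 to 47472168) rose from 1.43 ± 2.52 to 382 ± 99.9, TLL2 from 1.23 ± 1.23 to 141 ± 25.4 and FYB1 from 1.12 ± 1.16 to 137 ± 34.9. GOLGA7B rose from 0.531 ± 0.884 to 77.5 ± 13.7, C9 from 5.22 ± 2.97 to 295 ± 52.3 and SLC6A13 from 0.337 ± 0.827 to 58.4 ± 8.49. With relacorilant alone C9 had a mean of 74.9 ± 6.45. PHF24 had no read with cortisol and 55.4 ± 33.7 with both compounds, at least 16.7-fold higher against 3 reads per library. TLL2 begins 4.19 kb after the end of the expressed gene TM9SF3 on the same strand, SLC8A2 15.5 kb after NAPA and SLC6A13 17.3 kb after KDM5A. FYB1, GOLGA7B and PHF24 begin 97.1, 89.3 and 705 kb after the nearest such gene.

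Of the glucocorticoid-induced list, 7 of 30 measured members rose and 18 fell (8 and 18 adjusted over the list alone). The list median was -0.50 (adjusted p = 0.0135, but adjusted p = 0.633 with an estimated correlation). KLF9 fell from 3649 ± 399 to 748 ± 129.6. Extracellular matrix genes were lower: 8 of 49 measured members rose and 30 fell (8 and 30 adjusted over the list alone). The median of the list was -0.76 (adjusted p = 0.000361, but adjusted p = 0.633 with an estimated correlation). FBN2 fell from 52904 ± 4107 to 9163 ± 1265, FBLN1 from 24773 ± 4784 to 3400.4 ± 565, the proteoglycan DCN from 54633 ± 8042 to 15076 ± 994 and MFAP4 from 8569 ± 1440.3 to 1722 ± 225. Inflammatory lists were lower as well. Of NF-kB response genes, 1 of 18 measured members rose and 12 fell (1 and 13 adjusted over the list alone), and of cytokines and chemokines, 1 of 15 measured members rose and 10 fell (1 and 10 adjusted over the list alone). Their medians were -0.54 and -0.94 (adjusted p = 0.0134 and 0.0180, but adjusted p = 0.633 for both with an estimated correlation). TNFAIP3 fell from 831 ± 153 to 229 ± 65.4, BIRC3 from 170.2 ± 31.02 to 30.3 ± 12.4, TSLP from 236 ± 63.3 to 30.8 ± 10.99 and CCL2 from 2053 ± 155 to 816 ± 244. The NF-kB and glucocorticoid-induced lists share 2 tested members, BIRC3 and NFKBIA, so the 2 lists are not independent. NFKBIZ and CSF1 had log2 fold changes of -1.21 and -1.22, and TNIP1 rose by 0.74 ± 0.05. Interferon response genes were lower: 2 of 21 measured members rose and 12 fell (2 and 13 adjusted over the list alone). Their median log2 fold change was -0.49 (adjusted p = 0.0288, but adjusted p = 0.633 with an estimated correlation). IFIT1 fell from 703 ± 72.5 to 179 ± 48.1, and OAS3, IFI44 and IFIH1 had log2 fold changes of -1.05, -2.59 and -1.07. The interferon call was lost with a minimum mean of 50 and with quantile normalisation (adjusted p = 0.0784 and 0.0514, 0.00386 to 0.633 over all alternatives). Among cell type markers, 3 of 7 endothelial genes rose and 2 fell, 2 of 7 epithelial genes rose and 0 fell, and 3 of 12 pericyte and smooth muscle genes rose and 3 fell (adjusted p = 0.880, 0.738 and 0.914). None of the 3 libraries that stood apart belongs to these groups. The 35 named genes that changed, chosen for passing, had 6 of 6 libraries with both compounds past the cortisol mean, and in 35 the groups did not overlap (0.216% by chance for genes not so chosen).

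**Figure D3:**
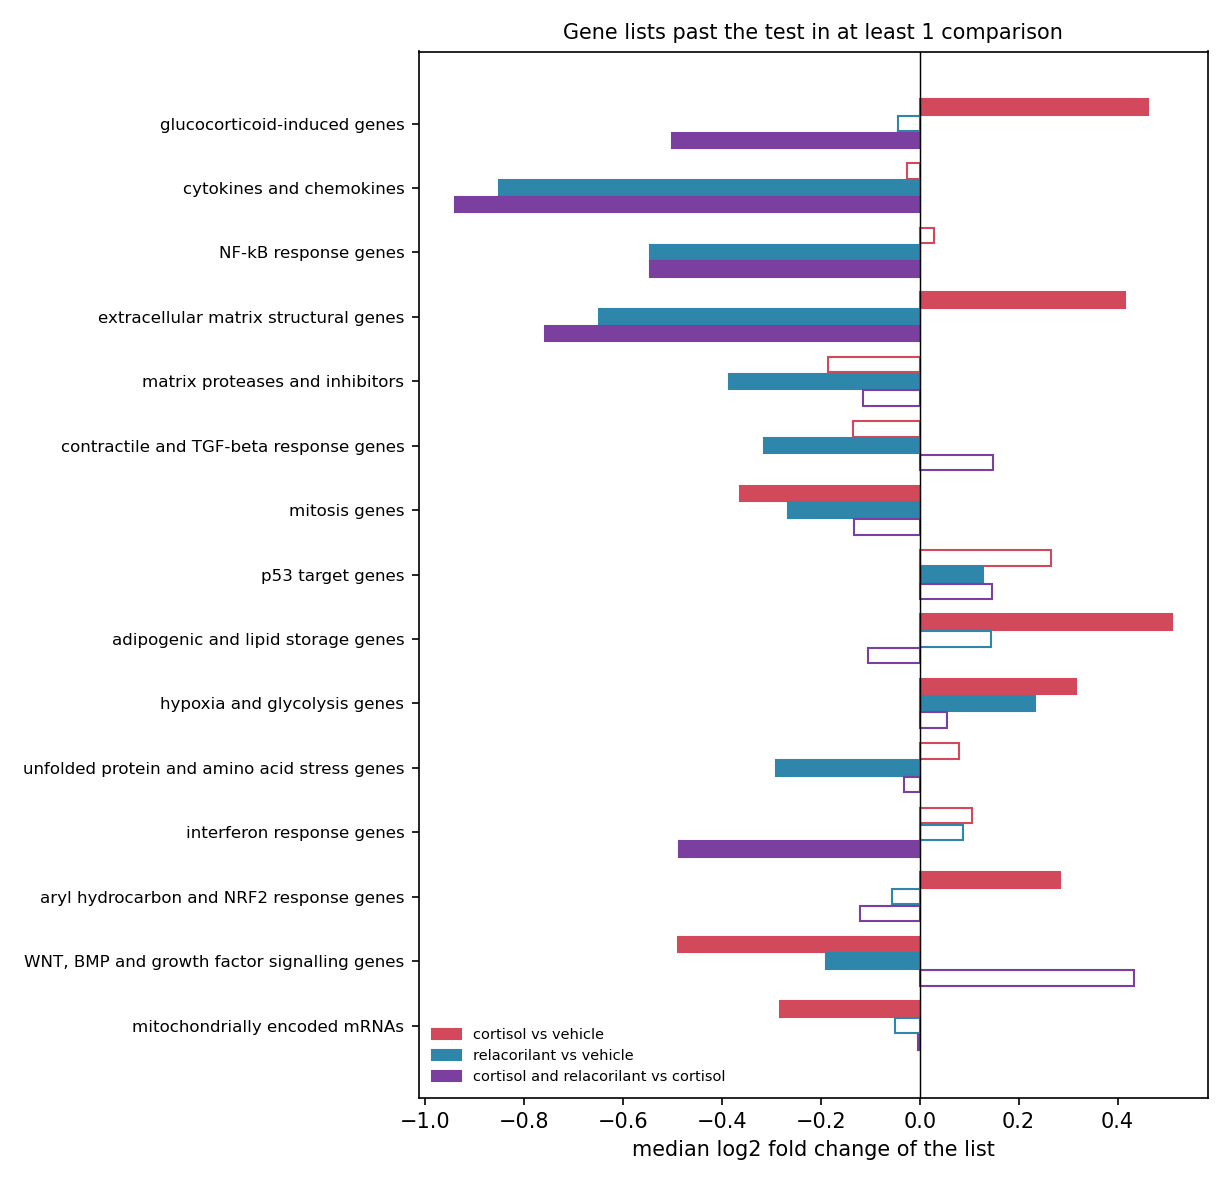
Median log2 fold change of the measured members of each gene list that passed the test in at least 1 of the 3 comparisons shown, with filled bars for lists past the test and open bars for those that did not pass. Glucocorticoid-induced genes had medians of 0.46 with cortisol and -0.50 when relacorilant was added to it.

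Cells given both compounds were compared with vehicle to describe all that differed, whether or not cortisol alone had changed it. Of the 15050 genes, 6742 differed, 3472 higher and 3270 lower, and 1572 by at least 2-fold. COL20A1 (ENSG00000101203, chromosome 20, 63293186 to 63334851) had no read with vehicle and 84.3 ± 19.5 with both compounds, at least 26.8-fold higher against 3 reads per library. It begins 3.39 kb after the end of the expressed gene ARFGAP1 on the same strand. SLC8A2, HSPA6, FYB1 and C9 were the other genes with the largest increases. ITGA8, TMEM176A, TMEM176B, FGL2 and LRP1B fell with log2 fold changes of -5.54, -5.23, -5.12, -4.45 and -4.28. FKBP5 and TSC22D3 were above vehicle (log2 fold change 0.72 ± 0.15 and 0.82 ± 0.11, adjusted p = 0.000223 and 2.22e-06). With relacorilant alone FKBP5 was above vehicle as well (log2 fold change 0.77), while TSC22D3 did not pass. PER1 did not differ past the threshold (adjusted p = 0.458), and NR3C1 was lower by a log2 fold change of -0.30 ± 0.08 (adjusted p = 0.00259). The 13 named genes that changed, chosen for passing, had 6 of 6 libraries past the vehicle mean, and in 12 the groups did not overlap (0.216% by chance for genes not so chosen). As lists, 9 passed against vehicle, and 0 of them did with an estimated correlation. Inflammatory genes were lower: of cytokines and chemokines, 0 of 15 measured members rose and 9 fell (1 and 9 adjusted over the list alone), and of NF-kB response genes, 2 of 18 measured members rose and 13 fell (3 and 13 adjusted over the list alone). Their medians were -1.26 and -0.64 (adjusted p = 0.00196 and 0.00196, but adjusted p = 0.469 and 0.469 with an estimated correlation). Of interferon response genes, 2 of 21 measured members rose and 9 fell (2 and 9 adjusted over the list alone), with a median of -0.51 (adjusted p = 0.0317, but adjusted p = 0.469 with an estimated correlation). Extracellular matrix genes and matrix proteases were lower as well: 8 of 49 measured members rose and 24 fell (8 and 24 adjusted over the list alone) in the matrix list, and 4 of 26 measured members rose and 12 fell (4 and 12 adjusted over the list alone) in the protease list. Medians of these lists were -0.34 and -0.21 (adjusted p = 0.00295 and 0.0317, but adjusted p = 0.696 and 0.379 with an estimated correlation). Among mitosis genes 0 of 37 measured members rose and 15 fell (0 and 15 adjusted over the list alone), and among mitochondrially encoded mRNAs 0 of 13 measured members rose and 4 fell (0 and 4 adjusted over the list alone). The medians stood at -0.44 and -0.30 (adjusted p = 0.00211 and 0.0307, but adjusted p = 0.735 and 0.696 with an estimated correlation). Hypoxia and glycolysis genes and p53 target genes were higher: 20 of 30 measured members rose and 1 fell (22 and 1 adjusted over the list alone) in the hypoxia list, and 10 of 26 measured members rose and 1 fell (10 and 1 adjusted over the list alone) in the p53 list. Here the medians were 0.38 and 0.27 (adjusted p = 0.000101 and 0.00884, but adjusted p = 0.469 and 0.379 with an estimated correlation). In the glucocorticoid-induced list 11 of 30 measured members rose and 7 fell (13 and 8 adjusted over the list alone), and the list did not pass (median 0.25, adjusted p = 0.440). Endothelial markers did not pass either (camera adjusted p = 0.425), but did so with no filter, with a median of 0.76 (camera adjusted p = 0.0353). Vehicle 4 lay -0.66, -0.42, -0.75, -0.55 and -0.06 from the other vehicle libraries in the means of the cytokine, NF-kB, interferon, matrix and protease lists. It lay 0.86, 0.08, -0.30 and -0.48 from them for mitosis genes, mitochondrially encoded mRNAs, hypoxia and p53 target genes. Without the 3 libraries that stood apart mitosis genes passed here (adjusted p = 0.0462, 1.79e-06 to 0.735 over all alternatives), although not for either compound alone against vehicle, and the protease list did not (adjusted p = 0.0551, 9.00e-05 to 0.379 over all alternatives). With a minimum mean of 50 the protease, interferon and mitochondrially encoded lists did not pass (adjusted p = 0.116, 0.0652 and 0.0588). Nor did the last with quantile normalisation, edgeR or the GC trend removed, and adjusted p ran over all alternatives from 3.24e-05 to 0.469 for interferon genes and 0.000337 to 0.696 for mitochondrially encoded mRNAs.

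Cells given both compounds were then compared with relacorilant alone, which gives the effect of cortisol in the presence of the antagonist. FKBP5 stood at 393 ± 33.6 with relacorilant and 382 ± 42.6 with both (log2 fold change -0.05 ± 0.15, adjusted p = 0.854), and PER1 did not pass either (adjusted p = 0.495). TSC22D3 rose from 449 ± 56.6 to 692 ± 49.0 (log2 fold change 0.63 ± 0.11, adjusted p = 0.000192). In all, 3860 genes changed, 2024 higher and 1836 lower, and 656 by at least 2-fold. HSPA6 rose from 14.8 ± 10.1 to 1319 ± 711, SLC8A2 from 15.0 ± 6.26 to 382 ± 99.9 and GOLGA7B from 3.26 ± 2.61 to 77.5 ± 13.7. NEB rose from 7.39 ± 3.71 to 133 ± 50.3 and the fructose transporter SLC2A5 from 4.77 ± 5.31 to 73.0 ± 24.1. LIMCH1 fell from 121 ± 49.2 to 3.36 ± 2.53, and NOC2LP1, PPP4R4, PCDHGA11 and MIR646HG had log2 fold changes of -3.37, -3.21, -3.07 and -2.74. NEB overlaps RIF1 on the opposite strand, and PCDHGA11 overlaps PCDHGC3 on the same strand. Of unfolded protein and amino acid stress genes, 11 of 26 measured members rose and 1 fell (12 and 1 adjusted over the list alone), and of contractile and TGF-beta response genes, 14 of 31 measured members rose and 1 fell (19 and 1 adjusted over the list alone). Both lists passed the test (medians 0.24 and 0.27, adjusted p = 5.48e-06 and 8.73e-06, but adjusted p = 0.320 and 0.255 with an estimated correlation). These were among 6 lists that passed. Matrix genes were higher than with relacorilant alone: 16 of 49 measured members rose and 2 fell (18 and 2 adjusted over the list alone). In the glucocorticoid-induced list 11 of 30 measured members rose and 3 fell (14 and 3 adjusted over the list alone), and the medians of the matrix and glucocorticoid-induced lists were 0.27 and 0.31 (adjusted p = 0.000636 and 0.0161, but adjusted p = 0.674 and 0.419 with an estimated correlation). Hypoxia and glycolysis genes were higher and interferon response genes lower: 9 of 30 measured members rose and 0 fell (9 and 0 adjusted over the list alone) in the former, and 1 of 21 measured members rose and 8 fell (1 and 9 adjusted over the list alone) in the latter. Their medians stood at 0.18 and -0.20 (adjusted p = 0.0161 and 0.0171, but adjusted p = 0.694 and 0.399 with an estimated correlation). Relacorilant 3 and relacorilant 4 lay -0.12 and -0.14 from the other relacorilant libraries over the stress list, -0.10 and -0.14 over the contractile list and -0.20 and -0.17 over the matrix list. They lay -0.05 and -0.24 from them over glucocorticoid-induced genes, -0.13 and -0.04 over hypoxia genes and -0.16 and -0.09 over interferon genes. The hypoxia call was lost without the 3 libraries and with quantile normalisation (adjusted p = 0.0532 and 0.118, 0.0103 to 0.694 over all alternatives). The 11 named genes that changed, chosen for passing, had 6 of 6 libraries past the relacorilant mean, and in 11 the groups did not overlap (0.216% by chance for genes not so chosen).

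The effects of cortisol without and with relacorilant were set side by side, from comparisons that share no library. Over the 5264 genes that changed with cortisol alone, the median ratio of the effect with relacorilant to that without was -1.63% ± 4.33 (SD over 1000 resamples of the libraries). Over the 1116 of these that changed by at least 2-fold it was 3.70% ± 3.00. Without the 3 libraries that stood apart these medians were -8.00% and -1.90%, and with the trend on GC content removed -5.07% and 0.719%. Over all alternatives the first ran from -8.00% to 0.671%. Across all tested genes, which are not independent replicates, the 2 sets of log2 fold changes had r = 0.036. Of genes changed in both comparisons, 724 went the same way (674 for independent lists) and 858 opposite ways (676 for independent lists). The test of the interaction found 4998 genes whose cortisol effect differed with relacorilant, 2586 with a positive and 2412 with a negative difference. With upper-quartile scaling these numbers were 2209 and 2804. As lists, contractile and TGF-beta response genes, WNT, BMP and growth factor genes and unfolded protein and amino acid stress genes had positive terms (medians 0.38, 0.54 and 0.27). Their adjusted p was 0.00153, 0.00307 and 0.0231, but adjusted p = 0.273, 0.273 and 0.630 with an estimated correlation. Members with positive and negative differences numbered 16 and 3 of 31, 18 and 3 of 38, and 13 and 6 of 26 (16 and 5, 19 and 5, and 14 and 6 adjusted over the list alone). The stress list did not pass with quantile normalisation (adjusted p = 0.0636, 0.00362 to 0.630 over all alternatives). Glucocorticoid-induced genes had a median of -0.40 and did not pass (adjusted p = 0.0544, 0.00168 to 0.600 over all alternatives, below 0.05 in 6 of them). FKBP5, ADH1B, MAOA and SLITRK5 had interaction terms of -3.81 ± 0.21, -8.28 ± 0.83, -6.64 ± 0.39 and -6.15 ± 0.57 on the log2 scale. TSC22D3 and PER1 had terms of -0.91 ± 0.16 and -1.10 ± 0.27. LIMCH1, with means of 2.08 ± 1.45, 66.5 ± 22.5, 121 ± 49.2 and 3.36 ± 2.53 with vehicle, cortisol, relacorilant and both, had a term of -9.43 ± 0.56. Positive terms were largest for HSPA6, NETO1, UNC13A, RTN1 and TLL2. RTN1, at 5.35 ± 0.39, had means of 484 ± 158, 48.1 ± 16.0, 62.1 ± 33.7 and 239 ± 55.1 with vehicle, cortisol, relacorilant and both.

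**Figure D4:**
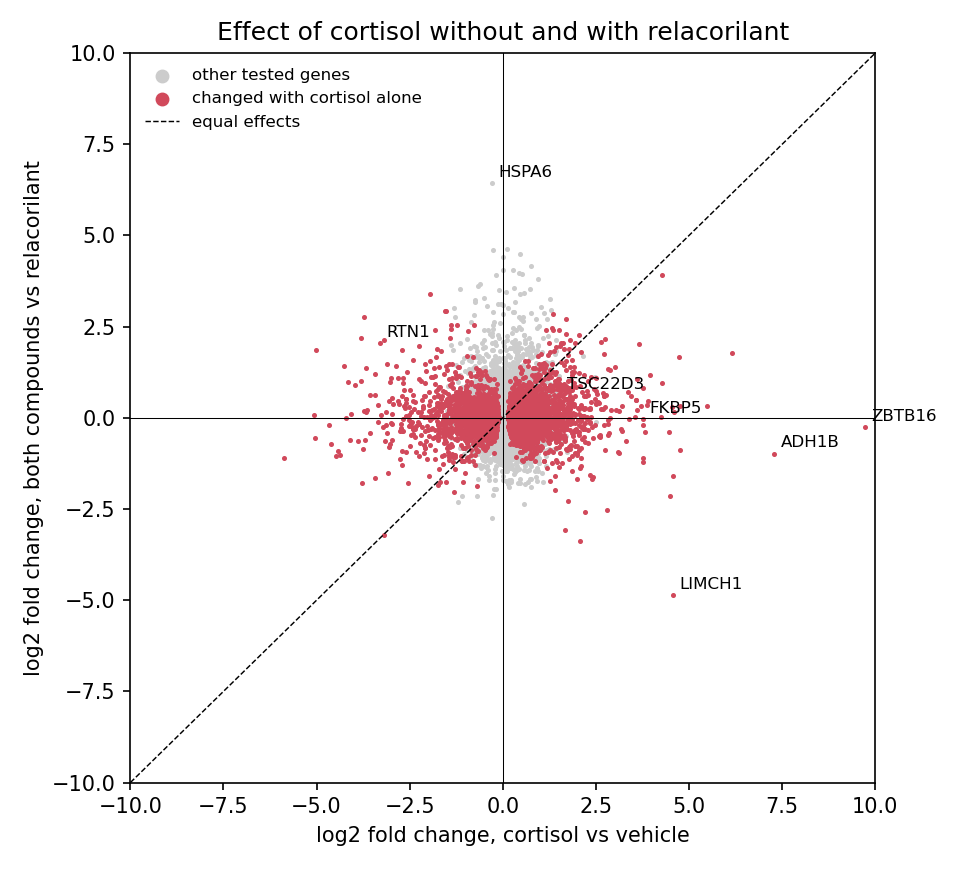
Log2 fold change of each tested gene for both compounds against relacorilant (vertical axis) and for cortisol against vehicle (horizontal axis), with 1 point per gene, the genes changed with cortisol alone in red and a dashed line where the effects are equal. The median ratio of the 2 effects over the 5264 red genes was -1.63%, and -8.00% to 0.671% over the alternatives.

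The effects of relacorilant without and with cortisol, which also share no library, had r = 0.416 across genes. Of genes changed in both, 1909 went the same way (868 for independent lists) and 415 opposite ways (869 for independent lists). Over the 3127 genes changed with relacorilant alone the median ratio was 0.900. Cortisol and relacorilant, each against the same vehicle libraries, had r = 0.297 and a covariance of 0.102. Unchanged groups simulated against shared controls gave 0.499 and 0.0299, and the covariance difference was 0.0722. The simulations used a spread per gene pooled over all groups, and not that of the vehicle libraries alone. Of genes changed by both, 1078 went the same way and 539 opposite ways (547 for independent lists in either case). With the vehicle libraries split between the comparisons in 20 ways, r averaged 0.157 (0.0707 to 0.244) and the covariance 0.0595. In these splits an average of 737 genes went the same way and 527 opposite ways (424 and 425 for independent lists).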

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

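The comparisons of depth and of the labels for the 3 libraries that stand apart were chosen only after the result was seen, as was the fit without them. Of 382 sets of 6 libraries, 36 held a library whose distance from the nearest other passed a cutoff. Independent normal values pass it in 1 of 20 sets, which gives 19.1. The sets are not independent, and in some, such as LINC02893 with vehicle, the other libraries all have 0, so that a few reads pass. The 19.1 is therefore no firm expectation. Vehicle 4, relacorilant 3 and relacorilant 4 held 19 of the 36.

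Vehicle 4 stood apart from the other vehicle libraries in PC2, at 93.7 against 18.7 to 37.6, and in PC3, at -40.6 against 28.0 to 37.0. Its slope of log2 level on GC content was -0.580 per 10 points, against -0.0506 to 0.0222. Its values were high for KIF23 (1519), TTK (459), KIF20A (1183), MT-ND2 (31913), NR3C1 (2411), POLH (1667) and LINC02893 (1.98, with 0 in the others). They were low for SREBF1 (580.3), ADM (2536), VEGFA (1722), HMOX1 (339.7) and IGF2 (56.4). Relacorilant 3 was low in PDIA4 (3781) and HYOU1 (2441), and relacorilant 4 high in BNIP3L (5682) and PDGFRA (3394).

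Vehicle 4, relacorilant 3 and relacorilant 4 shared a lower level of GC-rich genes, with slopes of -0.580 to -0.278 per 10 points against -0.0506 to 0.0560 in the other 21 libraries, and more mitochondrial reads, 5.01% to 5.13% against 2.90% to 4.00%. Library depth was argued against, since 9 other libraries lay within the range of depths of the 3, and so were mislabelled samples, since 0 of the 3 were closer to another group than to their own. That closeness was over the genes that differed most between groups as labelled, with the 3 libraries included. The own-group mean for relacorilant 3 held relacorilant 4, and the reverse. Both choices lean towards the given labels. A bias on GC content may be part of the pattern and stays open. Removing the GC trend took the mean residual correlation of vehicle 4 with the other 2 from 0.410 to 0.254, between the bounds of 0.1 and 0.3 set in advance. No biological explanation was tested, since the design gives none.

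Single libraries stood apart from their group in other values. Cortisol 1 had 17810712 reads, against 21679712 to 23705776, and a low PKM (47689). Cortisol 2 was high in DDIT4L (8.10) and SLC6A13 (2.02), and cortisol 5 in LINC01915 (3.24), CYP1B1 (2029.8) and SLC8A2 (6.47). Vehicle 1 was low in MT-ND5 (43537) and high in FYB1 (3.05), and vehicle 2 high in P4HA2 (4553). Relacorilant 1 was high in SLC2A5 (15.6, against 2.51 to 2.82 in the others) and relacorilant 6 in COL11A1 (281.7). With both compounds, replicate 1 was low in C1QL1 (3.21), replicate 2 high in TNIP1 (5942), replicate 3 high in TMEM176B (6.17) and SLITRK6 (5.14), and replicate 4 high in TMEM176A (4.51).

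The effect of cortisol differed with and without relacorilant for 4998 genes by the test of the interaction. Of 100 splits of the libraries, the real one included, 2 gave a count as large, and the highest other split gave 5615. These splits exchanged labels between cortisol and the combination and between vehicle and relacorilant. They therefore also broke up the effect of relacorilant itself, and cannot tell whether chance gives as many genes with an interaction.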

How the results depend on the processing

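The fit without vehicle 4, relacorilant 3 and relacorilant 4, the removal of the GC trend, the share of the cortisol effect in fits of only the groups compared or with a block, and the alternatives for lists in the combination against vehicle and against relacorilant and in the interaction were chosen only after the result was seen. Of 154 values of the counts of genes, counts of lists and the share of the cortisol effect over 12 settings and the estimated correlation, 138 stayed within the spread or within 1.5 times, and 16 did not. With no filter 13 lists moved with cortisol and 18 with relacorilant, against 8 and 10, and 10 in the combination against relacorilant, against 6. In the interaction 3 lists moved, against 6 with no filter, 6 with a minimum mean of 50, 5 with a pseudocount of 5, 5 with the GC trend removed and 7 with edgeR. A fit of only the vehicle and relacorilant libraries called 2034 genes, against 3127. With an estimated correlation 3 lists moved with cortisol, 1 with relacorilant and 0 with the combination against cortisol, vehicle or relacorilant or in the interaction, against 8, 10, 5, 9, 6 and 3. Without the 3 libraries the share of the cortisol effect left with relacorilant was -8.00% (-0.0800 as a ratio), against -1.63%, and over genes changed by at least 2-fold it was -1.90%, against 3.70%. With the GC trend removed these were -5.07% and 0.719%. The cause was not tested for any of these. Of 2194 values of named genes, 2185 kept their direction and their side of the threshold, 5 fell short of it, 4 came past it and 0 reversed. The exceptions were values of NR3C1, KIF20A and MT-CO3 given in the report. Most named genes were chosen on the same data for a large change or a small p, so that few exceptions were likely from the start. Over all genes, the fit of only the vehicle and relacorilant libraries kept 2000 of the 3127 calls.

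Without the 3 libraries 6205, 4164 and 9718 genes changed with cortisol, with relacorilant and in the combination against cortisol, of which 4986, 2846 and 8357 were among those of all 24 libraries. With the GC trend removed the counts were 5993, 3855 and 9075. The contractile list then passed with cortisol in both settings (adjusted p = 0.0230 and 0.0265, 0.00783 to 0.545 over all alternatives). Without the 3 libraries mitochondrially encoded mRNAs and cholesterol synthesis passed with relacorilant (adjusted p = 0.000550 and 0.0221, against 0.220 and 0.0802; ranges 0.000550 to 0.779 and 0.0221 to 0.592). The count tests gave 5198, 3106 and 8355 genes with edgeR and 5483, 3479 and 8541 with DESeq2. With upper-quartile scaling the share of changed genes that were higher was 52.6% with cortisol and 46.6%, 47.5% and 43.7% in the combination against cortisol, vehicle and relacorilant, against 49.0%, 51.1%, 51.5% and 52.4%. With relacorilant 1651 genes were then higher and 1489 lower, against 1562 and 1565. For the interaction 44.1% were positive, against 51.7%. With no filter 57.1%, 60.8% and 61.8% were higher in the combination against cortisol, vehicle and relacorilant.

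With the replicate number as a block, 5396, 3211, 8463, 6895, 3967 and 5108 genes changed in cortisol, relacorilant, the combination against cortisol, vehicle and relacorilant, and the interaction. No pairing of the libraries by number was seen: the deviations of 36 same-numbered pairs correlated at -0.183 to 0.403, 4 of them above 0.1, and 2 of 24 libraries correlated best with their own number. Both extremes involve libraries that stood apart, vehicle 4 with relacorilant 4 (0.403) and vehicle 3 with relacorilant 3 (-0.183). A weak effect shared by a number could be missed this way. The block changed the call of NR3C1 and of the aryl hydrocarbon and NRF2 list with cortisol, as given in the report, and of no other named gene or list. Depth limits genes with few reads: for a group with no read the floor of 3 reads per library is 2.66 to 3.31 normalised reads.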

Other observations

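The list of heat-shock genes, its comparison of GC content, that of single libraries the neighbour tests against vehicle and relacorilant and the test of gains per kb of gene were chosen only after the result was seen. Heat-shock chaperones and co-chaperones were higher with both compounds than with relacorilant alone. Of 24 listed genes, 20 rose and 0 fell (21 and 0 adjusted over the list alone). The median log2 fold change was 0.54 (camera p = 4.06e-19, and p = 0.000459 with an estimated correlation). Against cortisol alone 22 rose and 1 fell, and against vehicle 22 rose and 0 fell, while 3 rose and 10 fell with cortisol and 6 rose and 1 fell with relacorilant. The interaction was positive for 19 and negative for 1 (median 0.80, camera p = 1.26e-13, and p = 0.00243 with an estimated correlation). Besides HSPA6, the genes given here were picked after their values were seen. HSPA1B had means of 389 ± 50.1, 428 ± 30.96, 519.7 ± 76.6 and 4234 ± 1119 with vehicle, cortisol, relacorilant and both (SD, n = 6), and HSPA1A, its near-identical copy, 736 ± 76.7, 623 ± 70.1, 851 ± 129.6 and 5408 ± 1533. The small heat-shock protein HSPB8 rose from 1294 ± 209.7 with relacorilant to 3172 ± 437 with both and HSPH1 from 3923 ± 379.6 to 9303 ± 803. The co-chaperone BAG3 rose from 4069 ± 264 to 8122 ± 634 and DNAJB1 from 3874 ± 326 to 7163 ± 1147. CRYAB had means of 519.9 ± 60.8 and 567 ± 115 and did not pass in this comparison (adjusted p = 0.610), but rose with relacorilant against vehicle (log2 fold change 1.44 ± 0.14, adjusted p = 1.55e-08). HSP90AA1 fell with cortisol from 34251 ± 8993 to 18592 ± 1723. The mean log2 level of the list was 11.09 in vehicle 4, against 10.76 to 10.91 in the other vehicle libraries.

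For the heat-shock pattern a bias on GC content was argued against, since the median against relacorilant was 0.536 with the GC trend removed. So was the weight of a few libraries, since 6 of 6 libraries with both compounds had a mean log2 level of the list (11.9 to 12.4) above the highest library of the other groups (11.2). A response of the cells to the 2 compounds given together stays open as a hypothesis, found on the same data and not tested on others.

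Genes with few reads were at least 2-fold higher with both compounds more often where an expressed gene lay upstream. Among 4314 genes with a mean below 100 that were not among the largest changes taken by the rule for named genes, the share higher by at least 2-fold against cortisol was 34.3% ± 2.69 (SE, 107 of 312) where a gene with a mean of at least 500 ended within 10 kb upstream on the same strand. It was 16.8% ± 0.773 (393 of 2339) with no such gene within 10 kb and 14.5% ± 2.79 (23 of 159) where one started downstream. The shares with and without an upstream gene were 10.6% and 8.98% with cortisol, 17.9% and 5.77% with relacorilant, and 39.4% and 12.6% against vehicle and 22.4% and 6.80% against relacorilant for the combination.

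The values are consistent with transcription running on from the upstream gene as a hypothesis, since the shares with such a gene (34.3%, 39.4% and 22.4% against cortisol, vehicle and relacorilant) exceeded those with none by 6.26, 9.42 and 6.47 SE and those with one downstream by 5.12, 6.14 and 4.44 SE. All SE of these shares are over genes, which are not independent, and hold no spread between libraries. The 3 comparisons also share the libraries given both compounds. Genomic DNA would add reads to silent genes by length. The 4560 silent genes taken were coding, at least 1 kb long and with means below 10 in the other groups. No expressed gene lay within 10 kb of them. Their gain per kb had a median of 0 and a 90th percentile of 1.01, 1.09 and 0.926 reads, and 41.0% had no read with both compounds. Its lower quartile was 5.18, 5.52 and 5.38 over 53 genes of that length and level, with any neighbours, that rose at least 2-fold against cortisol. These 53 were chosen for their rise and a mean of at least 10 over the 24 libraries, so their larger gain was set by the choice. The gains of the 4560 argue against an addition by length, even across silent genes, as large as these rises. Among the 2339 genes above with no expressed neighbour, 16.8% were higher and 16.6% lower against cortisol (a difference of 0.157 SE), but more were higher than lower against vehicle (12.6% and 10.3%, 2.39 SE) and relacorilant (6.80% and 4.53%, 3.36 SE). A smaller addition from genomic DNA (mean gains of 0.319, 0.383 and 0.332 per kb), neighbours regulated together and the unknown strand of the reads stay open.

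Other splits of the same libraries were fitted, 100 per comparison with the real one included. For counts of changed genes 1 split, the real one, gave a count as large in 5 comparisons. These were 5264 genes against at most 2413 with cortisol, 3127 against 1345 with relacorilant, 8360 against 4850 for the combination against cortisol, 6742 against 2908 against vehicle and 3860 against 857 against relacorilant. Chance is thereby argued against only as finely as 100 splits allow, without adjustment for the several counts tried. Splits cannot tell a treatment from handling or a batch shared by its libraries. For counts of gene lists chance is not excluded with cortisol, where 8 lists moved and 10 splits gave as many, up to 12. Nor is it for the combination against cortisol, where 5 lists moved and 55 splits gave as many, up to 12. With relacorilant 10 lists moved and 4 splits gave as many, up to 11. That share is below 0.05 but is not adjusted for the several counts of lists tried, so chance is not firmly excluded. The other splits moved a median of 4, 3 and 5 lists with cortisol, with relacorilant and in the combination against cortisol.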
